A study of Mus musculus with 12 samples.

How the data were processed

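RNA was measured from 12 samples of cultured fetal mouse kidneys of the C57BL/6 strain, 6 labelled wildtype and 6 labelled beta-catenin activated. Per the labels' protocols, pregnant mice received tamoxifen by intraperitoneal injection at 10.5 dpc (days post coitum), at 2 mg per 40 g of body weight. Kidneys were dissected at 10.5 dpc and kept for 3 to 4 days on porous membranes, in a serum-free medium with transferrin and insulin at 5 µg/mL each and selenium at 5 ng/mL. The labels do not say which kidney had 3 and which 4 days. Total RNA was extracted with Trizol and labelled with an Affymetrix kit for 3' expression arrays, per the labels' protocols. The labels also list a pair of fluorescent dyes that such a kit does not use; each array here holds a single value per probe set, and the dye entry was not used.

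The deposited table holds an intensity on a linear scale for each of 22690 probe sets and each array. The values run from 0.0693 to 23037.5. After trimming 2% from each end, every array has the same mean, between 250.099 and 250.126, so the deposited intensities had been scaled per array. The software that summarised and scaled them is not given in the sources used here. There are no detection calls in the values used here; signal over background was judged from 27 probe sets for bacterial control transcripts, which read at most 29.0, or 5.49 as log2(intensity + 16).

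Before the data were examined, the grouping, the tests, 24 gene lists, the rule for naming genes and the alternatives were fixed. Intensities were taken as log2(intensity + 16), so fold changes of dim genes are understated. Quantile normalisation was to be applied only if array quartiles differed by more than 0.1; they differed by 0.25 at the lower quartile, 0.29 at the median and 0.18 at the upper quartile, so it was applied. Gene names came from the platform annotation in the form given with the data. Of the probe sets, 20380 had 1 gene symbol, 691 had several and 1555 had none listed, and 64 were controls. The last 3 classes were left out. Of 12393 gene identifiers, 12369 were found in the RefSeq gene table of assembly GRCm38.p6, and 0 of these had another symbol there. A gene with several probe sets (4956 genes) was represented by the probe set with the highest mean over all 12 arrays. No genome build is named for the array, so no coordinates are given.

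Activated and wildtype kidneys were compared with limma 3.58.1 in R 4.3.3, by a linear model with moderated variances that follow a trend with signal, with Benjamini-Hochberg adjustment over 12393 genes and a threshold of 0.05 on the adjusted p. Fold changes are activated minus wildtype on the log2 scale with the moderated standard error (SE). The sample titles carry numbers that fall into 2 runs, 3014 to 3020 and 3109 to 3115, with 3 wildtype and 3 activated arrays in each. They are called the lower and the higher run here; what the numbers stand for is not given in the labels. The run was planned as a term of the model, as separate fits of 3 against 3 arrays, and as an interaction with genotype. Replicates 1 to 3 of each genotype are in the lower run and 4 to 6 in the higher run; these replicate numbers only name the arrays and pair none of them.

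The lists, 440 memberships in all with 393 measured, were tested with limma's camera at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 24 lists. Camera with a correlation estimated for each list, and fry, were the other tests. The named genes were Ctnnb1, Igf2, Six2, Wt1 and Myod1, up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold with no overlap between the groups, and up to 4 members of each list with the smallest adjusted p. This rule gave 100 genes. A further 47 genes and any others outside the rule were chosen after their values were seen, and the text says so where they appear. The alternatives fixed at the start were the values as deposited, arrays centred on their medians, removal of the dimmest 40% of genes, the mean of all probe sets of a gene, every probe set tested alone, other variance settings, array weights, a covariate of Y-linked signal, a pseudocount of 1, stricter thresholds and leaving out each array. Added after seeing the data were a covariate for the ratio of 5' to 3' control signal, removal of activated 2 with wildtype 2, the repetition of the alternatives for the other counts, a pooled spread over runs, an effect averaged over runs, and an exact permutation test of list means. Plots were drawn with matplotlib 3.10.9.

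The calculations were tested on simulated data, with 200 genes changed by known amounts. The changed genes were drawn only from the brighter genes, so the shares recovered do not hold for dim genes. Except for the interaction, each changed gene was shifted by the same amount in both runs. The shares over all 12 arrays and with the run as a term therefore do not hold for genes whose change differs between the runs. They also depend on 200 genes being changed at once, since the adjustment is stricter when fewer genes change. In the comparison of all 12 arrays, 23.9% of genes shifted by 0.5, 88.1% of genes shifted by 1 and 98.5% of genes shifted by 2 on the log2 scale were recovered among 12393 genes. In the lower run alone the shares were 7.46%, 58.2% and 92.4%, in the higher run alone 11.9%, 64.2% and 97.0%, with the run as a term 32.8%, 85.1% and 98.5%, and for the interaction 2.99%, 44.8% and 93.9%. Genes left unchanged made up 0 of 140 calls over all 12 arrays, 3 of 108 in the lower run and 3 of 118 in the higher run. With the run as a term they made up 9 of 153 calls, and for the interaction 4 of 98. A shift of 0.5 put on the Wnt/beta-catenin target list alone was called, with 0 other lists. The simulated noise was independent between genes, so this says nothing about list calls that correlation between genes can cause.

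Log2 values of the 12 arrays correlated at 0.947 to 0.981, and there were 0 pairs of identical columns. The labels do not say that the arrays came from separate animals or cultures, so the p-values measure the spread between these samples, which may be partly technical. The number of arrays limits the precision.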

Results

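The study compared gene expression in cultured fetal mouse kidneys with and without activation of beta-catenin, the protein that carries the canonical Wnt signal to the nucleus. There were 6 wildtype and 6 activated samples, each measured on an array of 3' probe sets, and 12393 genes were tested. The labels do not say that the samples came from separate animals or cultures, and a sample need not be a single kidney. The sample titles form a lower and a higher run of numbers, each with 3 wildtype and 3 activated arrays. The labels do not say what the runs are, so each result is given over all 12 arrays and then by run.

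The arrays separated more by run than by genotype. The first principal component, with 24.7% of the variance, lay between -27.1 and -15.0 in the lower run and between 17.0 and 22.9 in the higher run. The second, with 17.7%, followed the ratio of 5' to 3' signal of the Gapdh and beta-actin control probe sets, a sign of RNA or labelling quality, with Pearson's r = -0.852 (permutation p = 0.0001) and Spearman's rho = -0.755 (permutation p = 0.00623) over the 12 arrays. Without the 2 arrays farthest from the median ratio r was -0.798, and within the runs it was -0.910 and -0.846. Activated 2 stood apart in this ratio, with a Gapdh log2 5'/3' ratio of 0.07 where the other arrays lay between -2.61 and -1.06. Its 5' and 3' signals were thus the most alike, so standing apart does not mean that this array was the poorer one. Y-linked genes averaged 4.30, 4.48 and 4.24 in wildtype 2, wildtype 5 and activated 6, where Xist, the transcript of the inactive X chromosome, read 11.88, 11.90 and 11.52. In the other arrays the Y-linked mean was at least 7.38 and Xist at most 6.08, except for activated 4, which had both a Y-linked mean of 7.54 and Xist at 10.90. On the second component wildtype 2, wildtype 5 and activated 6 lay at -20.5, -17.7 and -24.7. Activated 2, with a Y-linked mean of 7.38, lay at -30.4, and the other arrays lay between -2.80 and 24.5. That component thus also followed the Y-linked signal in part.

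Apcdd1 encodes a membrane-bound inhibitor of Wnt signalling. Over all 12 arrays it rose from 10.15 ± 0.41 in wildtype to 12.14 ± 0.69 in activated kidneys (log2 intensity, SD, n = 6 arrays each), a fold of 3.98. Gask1b, which encodes a Golgi-associated protein, rose from 7.42 ± 0.17 to 8.48 ± 0.26. Calb1, the calbindin gene that marks the ureteric bud and its tips, fell from 11.54 ± 0.17 to 10.79 ± 0.26. In each of the 3 genes all 6 activated arrays lay on the same side of all 6 wildtype arrays. Gask1b is in no list and was named by the rule for called genes.

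These 3 of 12393 genes were all that passed limma's test at an adjusted p of 0.05, and 762 genes (6.15%) had an unadjusted p under 0.05. The log2 fold change was 1.99 (SE 0.27, adjusted p = 0.0146) for Apcdd1, 1.06 (SE 0.14, adjusted p = 0.0146) for Gask1b and -0.75 (SE 0.12, adjusted p = 0.042) for Calb1. The 4 probe sets of Apcdd1 gave 1.84 to 2.20, and the second probe set of Calb1 gave -0.62. Other targets of the Wnt pathway did not pass. Wif1, which encodes a secreted Wnt inhibitor, differed by 2.80 (SE 0.50, adjusted p = 0.105), with a wildtype mean of 4.84 under the highest bacterial control signal of 5.49, and Axin2, a feedback inhibitor of the pathway, by 1.12 (SE 0.33, adjusted p = 0.475). Kremen1 differed by 0.77 (SE 0.21, adjusted p = 0.345), with both means, 4.57 and 5.34, under that control signal. Six2, which keeps nephron progenitors undifferentiated, differed by -1.15 (SE 0.37, adjusted p = 0.542), and Uncx, another gene of these cells, by -0.99 (SE 0.20, adjusted p = 0.215). Wt1 (-0.28), Igf2 (-0.08) and Myod1 (-0.32) did not pass; both Myod1 means, 5.19 and 4.87, lay under the bacterial control signal. Groups did not overlap in 62 genes, 0.50% of those tested, where chance gives 0.217%. With limma, 0 genes passed without wildtype 1, wildtype 3, activated 1 or activated 3 (729, 710, 686 and 663 at an unadjusted p under 0.05), and 1 passed without activated 2. On the values as deposited or centred on array medians, 2 genes rose and 0 fell. Models that hold the run called more: 13 genes with the run as a term, 48 (40 up, 8 down) with the 5' to 3' control signal beside it, and 105 (67 up, 38 down) for the effect averaged over the runs beside an interaction, of which the last 2 were chosen after the data were seen.

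Ctnnb1, the gene of beta-catenin itself, was at 12.97 ± 0.10 in wildtype and 12.92 ± 0.06 in activated kidneys, a difference of -0.05 (SE 0.06, adjusted p = 0.958). Its other 2 probe sets gave -0.27 and -0.13 and did not pass either. An activating change in the protein need not alter the level of the transcript, so these values check nothing about the labels.

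With the run as a term of the model, 13 genes passed, the same 3 among them. Those that rose were Wif1 (adjusted p = 0.0134), Nkd2, Mab21l1, Apcdd1, Gask1b, Car7, Dpysl3, Dcn, Sgk1 and Bgn, and those that fell were Gas1, Ank3 and Calb1. Car7 had both means, 4.39 and 5.34, under the bacterial control signal of 5.49, and Wif1, Mab21l1 and Nkd2 had wildtype means of 4.84, 4.23 and 5.47, so the size of these changes is uncertain. Nkd2 is a Wnt antagonist of the naked cuticle family and Dcn and Bgn encode small proteoglycans of the matrix; apart from Wif1, Apcdd1, Gask1b and Calb1, these genes were chosen after their values were seen. In this model 4 to 20 genes passed without single arrays (5 without wildtype 1, 7 without wildtype 2, 20 without wildtype 6, 4 without activated 1 or activated 3). It gave 8 genes, 7 up and 1 down, with arrays centred on their medians, and 1 without the variance trend.

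**Figure D1:**
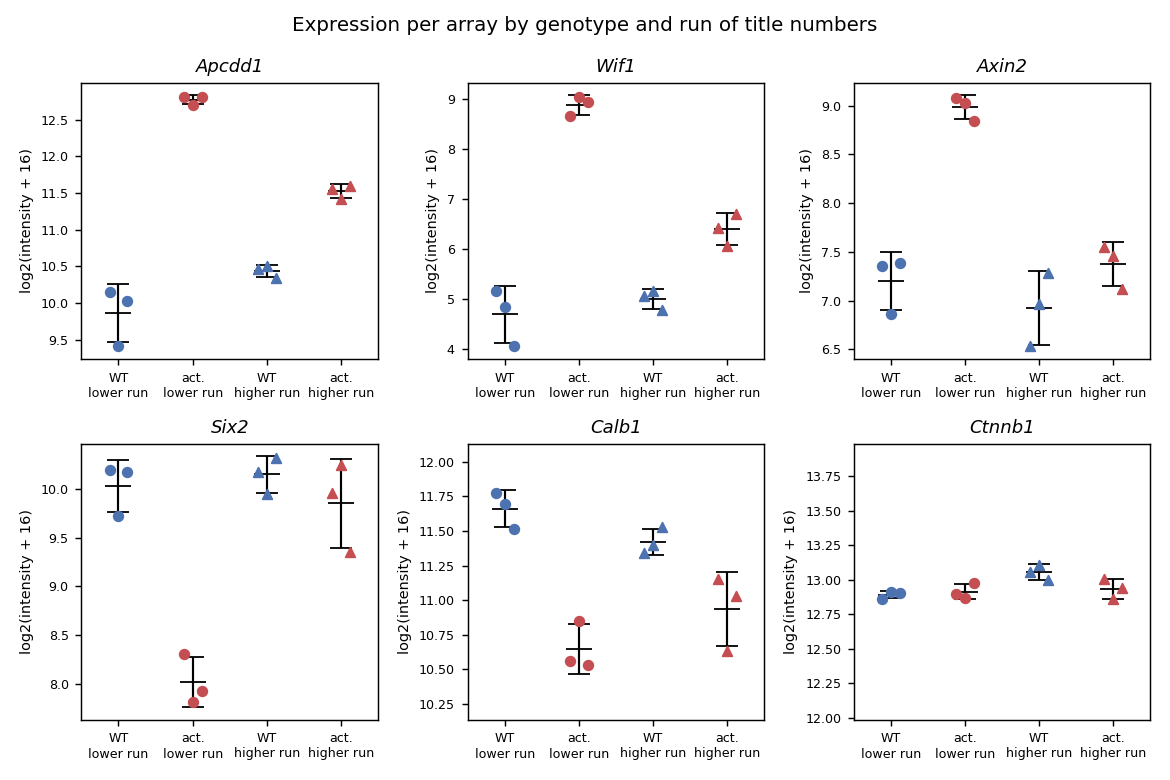
Expression of 6 genes on each array as log2(intensity + 16), with wildtype (WT) in blue and activated (act.) in red, circles for the lower and triangles for the higher run of title numbers; bars are means ± SD of 3 arrays. Apcdd1 and Wif1 lie higher in activated kidneys of both runs and by more in the lower run (2.91 and 4.20 against 1.08 and 1.40), Six2 and Axin2 part mainly in the lower run, and Ctnnb1 lies near 13 on every array.

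As lists, targets of the Wnt/beta-catenin pathway rose and genes of nephron progenitors fell. The 19 measured Wnt targets averaged 0.78 higher in activated kidneys (camera, adjusted p = 2.08e-09; adjusted p = 0.141 with an estimated correlation), and 15 of the 19 had a positive difference. Among them 1 gene, Apcdd1, rose over all genes tested, and 9 rose adjusted over the list alone. The 20 progenitor genes averaged -0.53 (adjusted p = 4.45e-09; adjusted p = 0.133 with an estimated correlation), and 2 of the 20 had a positive difference. None of them passed over all genes, with 6 down adjusted over the list alone; the members with the smallest adjusted p were Uncx, Meox1 (-0.94), Capn6 (-1.06) and Six2.

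Another 5 lists passed camera. The endothelium list averaged 0.29 higher (adjusted p = 2e-05; adjusted p = 0.141 with an estimated correlation), with 15 of 17 members positive and Sox17, a transcription factor of arterial endothelium, at 0.73 (SE 0.21, adjusted p = 0.388). The hypoxia and glycolysis list averaged 0.29 higher (adjusted p = 1.63e-05; adjusted p = 0.141 with an estimated correlation), with 14 of 16 positive. The BMP and TGF-beta response list averaged 0.33 higher (adjusted p = 0.000332; adjusted p = 0.141 with an estimated correlation), led by Bmp4 at 1.25 and the homeobox genes Msx2 at 1.43 and Msx1 at 0.84. The proximal tubule list averaged -0.28 (adjusted p = 0.00862; adjusted p = 0.342 with an estimated correlation) and the ureteric bud and collecting duct list -0.19 (adjusted p = 0.013; adjusted p = 0.27 with an estimated correlation). Over all genes, 1 member of these 5 lists passed, Calb1. Adjusted over the list alone, 1 rose in the endothelium list, 0 in the hypoxia list and 3 in the BMP list, and 0 fell in the proximal tubule list and 1 in the ureteric bud list.

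So 7 of 24 lists were called by camera at the preset correlation and 0 with an estimated correlation (5 at an unadjusted p under 0.05). Fry's test for a shift in 1 direction called 0 (6 at an unadjusted p under 0.05). Its test for changes in either direction, which does not show a shift of a list, passed for Wnt targets and nephron progenitors (adjusted p = 0.0262 each). It also passed for the stroma and the neuron, glia and neural crest lists (adjusted p = 0.0394 each). In an exact permutation test of the list means over all 924 assignments of the 12 arrays, chosen after the data were seen, the Wnt target and nephron progenitor lists each had p = 0.00216, the smallest that the test can give, and an adjusted p of 0.026; no other list passed it. Within the runs, with 400 assignments, both had the smallest possible p of 0.005 and an adjusted p of 0.06.

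The effect of activation was larger in the lower run. There, Wif1 rose by 4.20 (SE 0.32, adjusted p = 0.000361), Apcdd1 by 2.91 (SE 0.17, adjusted p = 0.000203) and Axin2 by 1.78 (SE 0.20, adjusted p = 0.00382), while Six2 changed by -2.01 (SE 0.19, adjusted p = 0.00155) and Capn6, a calpain-family gene of the cap mesenchyme list, by -1.98 (SE 0.15, adjusted p = 0.000361). In the higher run the same genes differed by 1.40 (SE 0.24), 1.08 (SE 0.09), 0.45 (SE 0.23), -0.29 (SE 0.21) and -0.14 (SE 0.15), and of these Apcdd1 passed (adjusted p = 0.00709). In the lower run 74 genes changed, 41 up and 33 down, and in the higher run 1 gene, Apcdd1. Respectively, 876 and 787 genes had an unadjusted p under 0.05.

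The genes that rose in the lower run included further parts of the Wnt feedback machinery, namely Nkd2 (3.54), the Wnt deacylase gene Notum (2.89) and the secreted inhibitor gene Dkk1 (2.80). Also among them were Bmp4 (2.06), Bmp2 (1.87), Msx2 (2.81), Mab21l1 (3.17), and the transcription factor genes Tfap2c (3.46) and En2 (2.43). The mitophagy gene Bnip3, of the hypoxia and glycolysis list, rose as well (1.25). Those that fell included the progenitor genes Meox1 (-1.52), Uncx (-1.50) and Traf1 (-1.71), and the stromal genes Foxd1 (-0.93), Meis2 (-0.83), Aldh1a2 (-1.09) and Ntn1 (-2.02), of which Foxd1 defines the stromal progenitors and Aldh1a2 makes retinoic acid. The largest fall was that of Dcx, a microtubule-binding protein gene known from migrating neurons, at -3.41 (SE 0.25, adjusted p = 0.000361). Some of these changes start or end under the highest bacterial control signal of 5.49, so their size is uncertain: the lower-run wildtype means were 4.69 for Wif1, 5.19 for Nkd2, 4.33 for Mab21l1, 4.46 for Tfap2c, 4.72 for En2 and 4.87 for Msx2, and the activated means 5.07 for Dcx and 4.45 for Traf1. Nkd2, Notum, Dkk1, Tfap2c, Mab21l1, En2, Bnip3, Traf1 and Ntn1 were chosen after their values were seen.

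The test of the difference between the runs called 41 genes, and in 40 of them the change was larger in size in the lower run; 34 of the 41 were also called in the lower run. The difference, higher minus lower run, was -1.83 for Apcdd1 (adjusted p = 0.00196), -2.79 for Wif1 (adjusted p = 0.00802), 1.72 for Six2 (adjusted p = 0.025), 1.84 for Capn6 (adjusted p = 0.00196), 0.99 for Aldh1a2 (adjusted p = 0.022), 3.21 for Dcx (adjusted p = 0.00034) and -2.77 for Msx2 (adjusted p = 0.022). It was -0.17 for Gask1b and 0.53 for Calb1, neither past the test, and -1.34 for Axin2 (adjusted p = 0.11). For Aldh1a2 part of the difference lay in wildtype, at 10.58 to 10.76 in the lower and 9.92 to 10.16 in the higher run. Its activated arrays lay at 9.39 to 9.67 and 9.80 to 10.09. Wildtype Foxd1 was likewise at 10.40 to 10.49 in the lower and 9.65 to 9.88 in the higher run. Over all 12393 genes, which are not independent replicates, the fold changes of the runs correlated at 0.131. Without any of the lower-run arrays except activated 2 the lower-run count was 30 to 37, and the interaction count was 16 to 27 without wildtype 1, 4, 5 or 6 or activated 1, 3, 4 or 5. With arrays centred on their medians the interaction called 18 genes, 3 up and 15 down, against 12 up and 29 down.

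**Figure D2:**
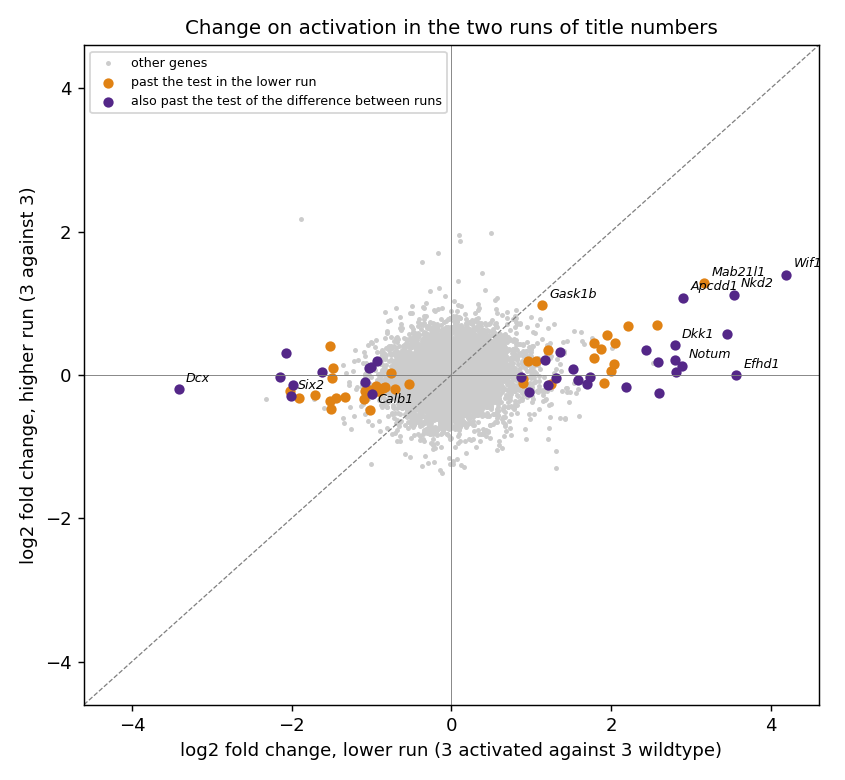
Log2 fold change on activation in the lower run (horizontal axis) against the higher run (vertical axis), 3 activated against 3 wildtype arrays in each. Grey points are genes that did not pass in the lower run, including some that passed the test of the difference between runs. Orange points are genes that passed in the lower run, and violet points those that also passed the test of the difference. The dashed line marks equal change. The 74 coloured genes were chosen by the lower-run test, which by itself favours larger changes in that run. Gask1b, Apcdd1, Nkd2, Mab21l1 and Wif1 lie well above the horizontal axis, at 0.97, 1.08, 1.12, 1.28 and 1.40 in the higher run.

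By run, the Wnt target list averaged 1.30 higher in activated kidneys of the lower run (adjusted p = 1.67e-17; adjusted p = 0.029 with an estimated correlation) and 0.27 higher in the higher run (adjusted p = 0.00115; adjusted p = 0.251 with an estimated correlation). In the lower run 5 of its 19 members rose over all genes and 8 adjusted over the list alone. The counts in the higher run were 1 and 2. The nephron progenitor list averaged -0.85 (adjusted p = 1.53e-12; adjusted p = 0.029 with an estimated correlation) and -0.21 (adjusted p = 0.00887; adjusted p = 0.267 with an estimated correlation). Of its 20 members 5 fell in the lower run over all genes, and 10 fell and 1 rose adjusted over the list alone; in the higher run 0 did by either count. For both lists every activated kidney lay beyond every wildtype kidney of its run, in both runs. The difference between the runs was -1.03 for the Wnt list (adjusted p = 1.79e-12; adjusted p = 0.00999 with an estimated correlation) and 0.64 for the progenitor list (adjusted p = 3.66e-07; adjusted p = 0.0127 with an estimated correlation).

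Hypoxia and glycolysis genes and BMP and TGF-beta response genes followed the same division. The first averaged 0.59 in the lower run (adjusted p = 4.67e-12; adjusted p = 0.029 with an estimated correlation) and -0.02 in the higher run, and the second 0.61 (adjusted p = 8.31e-07; adjusted p = 0.029 with an estimated correlation) and 0.05. In the lower run Bnip3 rose over all genes and 9 of 16 hypoxia genes rose adjusted over the list alone, and 2 BMP response genes, Bmp4 and Msx2, rose over all genes and 4 adjusted over the list alone. The early nephron list averaged 0.36 in the lower run (adjusted p = 0.00117; adjusted p = 0.0681 with an estimated correlation), where Bmp2 rose, and -0.06 in the higher run. The stroma list averaged -0.27 in the lower run (adjusted p = 0.00117; adjusted p = 0.0681 with an estimated correlation) and 0.11 in the higher run (adjusted p = 0.0314; adjusted p = 0.265 with an estimated correlation). It was mixed in the lower run, where 7 of its 20 members had a positive difference. There, 4 fell over all genes, and 2 rose and 5 fell adjusted over the list alone. Its member Dcn rose in the model with the run as a term. All 4 lists differed between the runs (adjusted p of 6.57e-10, 0.000207, 0.000398 and 1.88e-08; with an estimated correlation, adjusted p = 0.0106, 0.0127, 0.0127 and 0.00443).

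The proximal tubule list differed the other way. It averaged -0.06 in the lower run and -0.50 in the higher run, where it fell (adjusted p = 1.58e-07; adjusted p = 0.243 with an estimated correlation) with every activated kidney below every wildtype kidney. There, Cubn, a receptor for filtered proteins, differed by -1.25 (SE 0.41), Ttc36 by -1.10 (SE 0.25) and Slc27a2 by -1.01 (SE 0.34), none past the test. The difference between the runs passed at the preset correlation (adjusted p = 0.00116; adjusted p = 0.0869 with an estimated correlation). Its members were dim: the list mean in wildtype was 5.27 in the lower run, where bacterial controls read up to 5.49, and 5.95 in the higher run, where they read up to 5.20. The endothelium list was higher in both runs, by 0.26 (adjusted p = 0.0213; adjusted p = 0.519 with an estimated correlation) and 0.32 (adjusted p = 3.98e-05; adjusted p = 0.179 with an estimated correlation), and the ureteric bud list lay at -0.16 (adjusted p = 0.205) and -0.23 (adjusted p = 0.00115; adjusted p = 0.267 with an estimated correlation). Neither differed between the runs (adjusted p = 0.669 and 0.545).

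**Figure D3:**
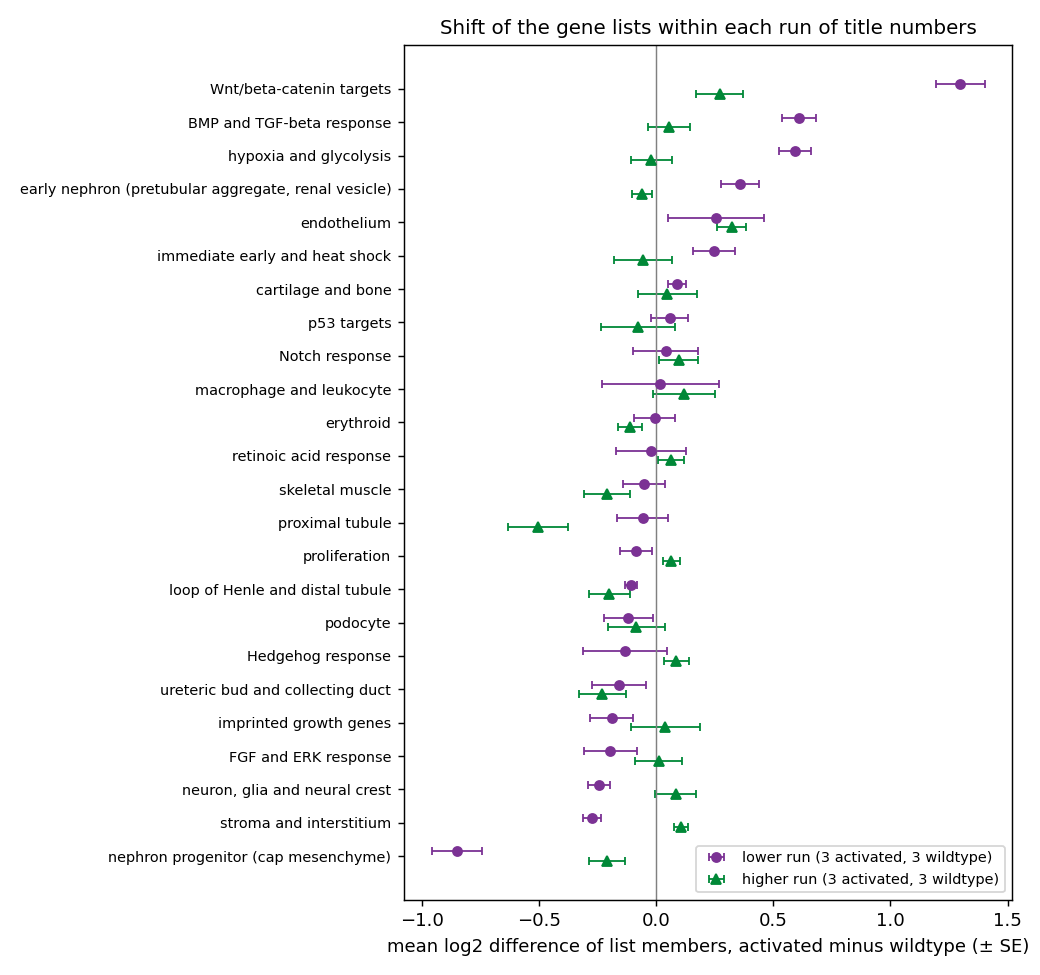
Mean log2 difference between activated and wildtype kidneys of the measured members of each of the 24 gene lists, for the lower run (violet circles) and the higher run (green triangles), with the SE over 3 arrays per group. The Wnt target list lies highest in the lower run, at 1.30, and the nephron progenitor list lowest, at -0.85; in the higher run the proximal tubule list lies lowest, at -0.50.

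The other 17 lists did not pass over the 12 arrays, with adjusted p from 0.0921 to 0.972. The mean difference was 0.15 for early nephron genes, -0.10 for podocyte genes, -0.15 for genes of the loop of Henle and distal tubule, -0.08 for stroma, -0.13 for skeletal muscle, 0.07 for cartilage and bone, 0.07 for macrophages and leukocytes, -0.06 for erythroid genes and -0.08 for neuron, glia and neural crest genes. It was -0.0095 for proliferation genes, 0.09 for immediate early and heat shock genes, -0.0098 for p53 targets, -0.08 for imprinted growth genes, and -0.09, 0.07, -0.02 and 0.02 for the FGF, Notch, Hedgehog and retinoic acid response lists. The mean and the median differed in sign for the stroma, neuron, proliferation, p53 and Notch lists, and camera's direction was opposite to the mean for the neuron and p53 lists. Among the single members, Dcx differed by -1.81 (SE 0.50, adjusted p = 0.388), Gap43, a growth cone gene, by 1.11 (SE 0.28, adjusted p = 0.345), and the imprinted genes Plagl1 and Mest by -0.32 (SE 0.08) and -0.42 (SE 0.12), none past the test.

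By run, besides the early nephron and stroma lists, 3 of these lists passed camera in a single run. The imprinted growth genes of the lower run averaged -0.19 (adjusted p = 0.0029; adjusted p = 0.0795 with an estimated correlation), with Plagl1 down by -0.53 (SE 0.08, adjusted p = 0.021), and the immediate early and heat shock genes 0.25 (adjusted p = 0.0364; adjusted p = 0.172 with an estimated correlation). In the higher run the skeletal muscle genes averaged -0.21 (adjusted p = 0.0314; adjusted p = 0.367 with an estimated correlation). The muscle list lay at a mean of 5.01 in wildtype of the lower run and 5.10 in wildtype of the higher run, under the highest bacterial control. Muscle genes did not differ between the runs in this shift (adjusted p = 0.396), while imprinted and immediate early genes did at the preset correlation (adjusted p = 0.00478 and 0.0356; adjusted p = 0.106 and 0.117 with an estimated correlation).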

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

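The tests with a covariate for the 5' to 3' control signal used an alternative added after the data were seen, the test of a common factor between the runs was chosen after the changes by run had been seen, the tests without single proximal tubule genes were chosen after those genes' values had been seen, and the splits within the runs for the lists after the splits over all 12 arrays.

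Among the 24 lists, 11 changed differently in the 2 runs of title numbers by a test of the interaction. Of the 41 genes called by that test, 7 are among those named by the fixed rule. As the shift in the higher run minus that in the lower run, Wnt/beta-catenin targets stood at -1.03, BMP and TGF-beta response genes at -0.55, hypoxia and glycolysis genes at -0.61, early nephron genes at -0.42, immediate early and heat shock genes at -0.30 and proximal tubule genes at -0.45. In the other direction, nephron progenitor genes stood at 0.64, stroma at 0.38, neuron, glia and neural crest genes at 0.33 (adjusted p = 0.0387; adjusted p = 0.111 with an estimated correlation), imprinted growth genes at 0.23 and proliferation genes at 0.15 (adjusted p = 0.0156; adjusted p = 0.16 with an estimated correlation). With an estimated correlation, 6 of the lists passed: Wnt targets, nephron progenitor, early nephron, stroma, hypoxia and BMP response. These 7 were Apcdd1 (-1.83), Wif1 (-2.79), Msx2 (-2.77), Six2 (1.72), Capn6 (1.84), Aldh1a2 (0.99) and Dcx (3.21).

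A smaller effect of activation in the higher run was weighed against RNA or labelling quality and against a smaller share of altered cells. With the 5' to 3' signal as a covariate, the run difference of the Wnt target list was -1.0 (SE 0.13), against -1.03 without it, which argues against that signal as the whole cause. If a single smaller share of altered cells accounted for the higher run, each gene's linear change there would be the same fraction of its lower-run change. The best fraction was 9%, which choosing genes by their lower-run change tends to lower. Of the 74 genes called in the lower run, 14.9% lay over 2 SE from it, between the bounds of 10% and 25% set for keeping or excluding this. The SE was that of the higher-run change alone, without the error of the lower-run change, which tends to raise this share. A smaller share of altered cells therefore stays open. The labels name neither a batch nor a difference in recombination or culture time between the runs, so these remain open too. Apart from the share of altered cells, no biological explanation was tested.

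The fall of the proximal tubule list in the higher run was weighed against dim signal and RNA quality. The 4 members above the bacterial control signal in wildtype of both runs averaged -0.033 (SE 0.156) in the lower and -0.45 (SE 0.156) in the higher run, but they moved both ways: Hnf4a by -0.74 and -0.82, Slc7a9 by -0.41 and -0.44, Slc5a2 by -0.0095 and -0.19 and Aqp1 by 1.03 and -0.34. Without Aqp1 the averages were -0.39 (SE 0.209) and -0.48 (SE 0.209), so the mean rests on 1 gene and a fall in the lower run hidden by background stays open, although the bound set beforehand for excluding it was met with all 4 genes. With the 5' to 3' signal as a covariate the higher-run shift was -0.49 (SE 0.11), against -0.50 without it, which argues against that signal as the whole cause. The call does not hold with an estimated correlation (adjusted p = 0.243), other differences between the runs stay open, and no biological explanation was tested.

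Other assignments of the arrays to groups were drawn to see whether chance gives as many calls. For the 3 genes over all 12 arrays, 3 of 100 splits gave as many, the real one included. That share lies under the limit of 0.05, but it is an estimate from the 100 splits drawn. It argues against chance without excluding it. The highest other split gave 16 genes. It put wildtype 1, 2 and 3 and activated 1, 3 and 5 together and so largely followed the runs. For the 7 lists, 18 of 100 splits gave as many and the highest other gave 13, but 15 of these 18 were unbalanced between the runs, where the real grouping is balanced. In splits within the runs, 5 of 100 gave as many as the real 7 lists with the run as a term (highest other 9), and 6 of 100 without it (highest other 7). The first lies at the limit of 0.05 and the second above it, so chance cannot be excluded for the number of lists called by camera. With the run as a term, 3 of 100 splits drawn within the runs gave as many as the real 13 genes, the real one included. This too argues against chance without excluding it. The highest other split gave 257 genes, many times the real count, which points to a structure of the samples: it grouped wildtype 1 and 6 with activated 1, 3, 4 and 5, all above 0 on the second principal component, which follows the 5' to 3' signal; of the arrays on the other side, wildtype 3 was also above 0. Wildtype 2, wildtype 5 and activated 6, the arrays with low Y-linked signal, were all on the other side, so that split also followed the Y-linked signal in part. With the 5' to 3' signal as a covariate beside the run, 48 genes passed, and with the Y-linked signal beside it 13 did. For the interaction, 4 of 100 regroupings gave as many as the real 41 genes. These regroupings shuffled the runs within each genotype, which mostly breaks up the difference between the runs and so widens the spread. They therefore cannot decide whether chance gives as many genes for the interaction. The highest gave 1418 and put wildtype of the lower run with activated kidneys of the higher run, which turns the difference between runs into the interaction.

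Within a run, 3 against 3 arrays make 10 splits, too few for a share under 0.05. For the lower run the real split gave 74 genes, matched by 1 of the 10, itself, and the highest other gave 0. For the higher run it gave 1 gene, 4 of the 10 gave as many, and the highest other gave 147; that split put wildtype 4, wildtype 5 and activated 6 together, the lowest of that run on the second principal component, which points to the same structure.

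In 14 of 258 tests a single array lay far from the others of its genotype, where chance flags about 5%. Wildtype 2 had a Gapdh log2 5'/3' ratio of -1.13 and activated 6 a Y-linked mean of 4.24. Among genes, wildtype 1 was low in Myod1 (4.34), wildtype 2 in Aif1 (4.20), Epor (5.59) and Mfng (4.74), wildtype 3 in Wif1 (4.05) and wildtype 5 in Meox1 (6.57), while wildtype 3 was high in Sox17 (8.89) and wildtype 5 in Rarb (8.75). Activated 1 was high in Myf5 (4.23) and activated 2 in Gap43 (7.26), and activated 5 was low in Cdh6 (5.43) and Tnnt3 (4.16). Of these values, those of Myod1, Wif1, Aif1, Mfng, Myf5, Tnnt3 and Cdh6 lay under the highest bacterial control signal over all arrays, 5.49.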

How the results depend on the processing

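Repeats for the run counts, the 5' to 3' covariate, the removal of activated 2 with wildtype 2 and the pooled spreads were added after seeing the data; where a value moved, the cause was not tested unless stated. The 3 genes over 12 arrays became 1 with the mean of all probe sets, without the variance trend, and without both activated 2 and wildtype 2; 0 at an adjusted p under 0.01 (limma, 762 at an unadjusted p under 0.05); 13 with the run as a term, 13 with the Y-linked covariate beside it and 48 with the 5' to 3' covariate beside it. It was 105 for the effect averaged over runs, and 74 and 1 in the lower and higher run alone. Without single arrays the count was 0 to 4 (0 without wildtype 1, wildtype 3, activated 1 or activated 3, 1 without activated 2). Gask1b passed in 21 of 26 alternatives, Apcdd1 in 17 (adjusted p 0.000203 to 0.145) and Calb1 in 9 (0.00496 to 0.552), none reversed. Calb1 lost its call without any single array except wildtype 4, activated 4 and activated 6 (adjusted p 0.0714 to 0.159), Apcdd1 without wildtype 1 or 3 or activated 1, 2 or 3 (0.0513 to 0.0676) and Gask1b without wildtype 1 or 3 or activated 1 or 3 (0.0513 to 0.0676).

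With the run as a term the 13 genes became 8 with median-centred arrays (7 up, 1 down) and with the mean of probe sets. They became 1 without the trend, 48 with the 5' to 3' covariate and 5 without both activated 2 and wildtype 2. Without single arrays they were 4 to 20 (5 without wildtype 1, 7 without wildtype 2, 20 without wildtype 6, 4 without activated 1 or 3). The lower run's 74 became 39 without the trend, 186 with array weights, 45 with the Y-linked covariate, 148 with the 5' to 3' covariate, 188 with the spread pooled over runs, and 30 to 87 without single arrays (36, 32 and 36 without wildtype 1, 2 and 3, 30 and 37 without activated 1 and 3). The higher run's 1 became 2 with median-centred arrays and with the pooled spread, 0 with the mean of probe sets and without the trend (749 and 772 at an unadjusted p under 0.05), 3 with robust variances, and 0 to 1 without single arrays (0 without wildtype 4, wildtype 6 or activated 4). The interaction's 41 became 18 with median-centred arrays, 24 without the trend, 88 with array weights, 87 with the 5' to 3' covariate and 16 to 47 without single arrays (27, 16, 18 and 25 without wildtype 1, 4, 5 and 6, 23, 16, 19 and 17 without activated 1, 3, 4 and 5).

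The 7 lists became 0 with an estimated correlation, alone or with the run as a term, and 0 by fry (5, 5 and 6 at an unadjusted p under 0.05), and were 5 to 8 without single arrays. Under estimated correlation and fry the mean shifts are the same by construction and no longer passed: Wnt targets 0.78, nephron progenitor -0.53, proximal tubule -0.28, ureteric bud -0.19, endothelium 0.29, hypoxia 0.29 and BMP response 0.33. The Wnt target, nephron progenitor and endothelium lists passed in the other 25 of 27 alternatives. The lower run alone gave no call for proximal tubule (-0.058) and ureteric bud (-0.16), and new calls for early nephron (0.36), stroma (-0.27), immediate early genes (0.25) and imprinted genes (-0.19). In the higher run alone stroma lay at 0.11 and passed, against -0.08, not passing, over all 12 arrays. Hypoxia lay at -0.020 (SE 0.0891) and gave no call. BMP response (0.055) gave no call either, and skeletal muscle (-0.21) gave a new one. Without the dimmest genes the loop of Henle list, with 3 of 15 members left, passed at -0.38, and what remained of the muscle list, Actc1 alone of 23, at -0.59; with the 5' to 3' covariate macrophage (0.19) and imprinted genes (-0.13) did. Without single arrays the proximal tubule list ranged from -0.36 to -0.20 (not passing without wildtype 4, 5 or 6: -0.23, -0.20 and -0.21), ureteric bud from -0.26 to -0.12 (not passing without wildtype 5 or activated 3, both -0.12), early nephron from 0.11 to 0.19 (passing without activated 4 or 5, both 0.19), macrophage from -0.079 to 0.22 (passing without activated 2: 0.22) and imprinted genes from -0.13 to -0.040 (passing without wildtype 4 or activated 6, both -0.13). Ctnnb1 did not pass under any alternative, with -0.07 to -0.02 without single arrays. Among values of named genes, 59 newly passed and 13 no longer passed when no single array was left out, and 1 and 18 without single arrays. Of 4278 values of genes and lists on the same side of the threshold, 105 that passed neither way changed sign. Camera was not run with robust variances, and removing the dimmest 40% of genes left no proximal tubule gene. Of the 12393 genes, 3927 had a mean under the highest bacterial control, where changes are compressed.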

Other observations

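The account of the wildtype arrays, its genes and the test of later nephron segments were chosen after the difference between the runs had been seen, and the bound of that test was changed after its result.

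Wildtype kidneys themselves differed between the runs of title numbers. Embryonic globin genes were lower in the higher run, Hbb-y by -1.89 (SE 0.10, adjusted p = 3.7e-05), Hba-x by -2.07 (SE 0.28, adjusted p = 0.0043) and Hbb-bh1 by -3.21 (SE 0.36, adjusted p = 0.0016); these were the called members of the erythroid list, which averaged -0.53 and did not pass (adjusted p = 0.253). Of 18 macrophage and leukocyte genes 7 were higher there, among them the lysozyme gene Lyz2 by 2.06 (SE 0.22, adjusted p = 0.0016) and the mannose receptor gene Mrc1 by 1.48 (SE 0.20, adjusted p = 0.0043). That list averaged 0.84 (adjusted p = 2.02e-08; adjusted p = 0.373 with an estimated correlation). Of 14 p53 targets 4 were higher, among them the cell cycle inhibitor gene Cdkn1a by 2.12 (SE 0.23, adjusted p = 0.0016) and Pmaip1 by 2.22 (SE 0.21, adjusted p = 0.00086). The p53 list averaged 0.72 (adjusted p = 1.77e-05; adjusted p = 0.373 with an estimated correlation). Of 16 immediate early and heat shock genes 6 were higher and 1 lower, with Fos at 2.12, Ier3 at 2.28, Hspa1b at 1.65 and Hsph1 at -0.74, and a list mean of 0.90 (adjusted p = 5.69e-07; adjusted p = 0.0942 with an estimated correlation). Of 19 proximal tubule genes 4 were higher, among them the endocytic receptor gene Lrp2 by 1.35 and Amn by 1.64, with a list mean of 0.69 (adjusted p = 1.94e-06; adjusted p = 0.0942 with an estimated correlation). Of 23 proliferation genes 5 were lower, with a list mean of -0.46 (adjusted p = 2.31e-08; adjusted p = 0.146 with an estimated correlation). The urothelial gene Upk3a (2.42) and the podocyte gene Podxl (1.29) were also higher, in lists that did not pass. Of 13 podocyte genes 2 were called higher and 1 lower.

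In all, limma called 632 genes between the 3 and 3 wildtype arrays, 410 higher and 222 lower in the higher run, 302 without the variance trend and 874 with the Y-linked covariate. Without wildtype 3, 4, 5 or 6 the count was 398, 227, 246 and 385. Camera called 5 lists, and with an estimated correlation 0 of 24 (3 at an unadjusted p under 0.05).

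A candidate explanation is that kidneys of the higher run had been in culture longer or were more mature, since the labels give 3 to 4 days without saying which. If so, later nephron segments could all be higher in their wildtype. The podocyte list lay 0.20 higher (SE 0.0742, camera adjusted p = 0.267) and the loop of Henle and distal tubule list 0.22 higher (SE 0.0760, camera adjusted p = 0.196). Both lie in that direction and neither passed. The bound first set took a miss of the threshold as evidence against, which it is not, so the explanation stays open, as does a technical batch. The runs were not labelled with either.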
